A study of Mus musculus with 6 samples.

How the data were processed

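RNA was measured in 6 libraries of lineage-depleted mouse bone marrow, 3 labelled Stag2KO and 3 labelled Stag2WT. Per the labels' protocols, marrow was depleted of lineage-marked cells with magnetic beads and RNA was extracted with TRIzol. The labels describe library kits only for other cell populations, so the kit used for these samples, and whether it keeps strand, is not given in the sources used here. The authors deposited 1 table of raw read counts per gene symbol, with a column per library. Per the submitters' processing notes, STAR 2.4, HTSeq 0.6.1 and DESeq2 were used with the mouse build mm9; the annotation and the strand setting are not given in the sources used here. Deposited counts were whole numbers with no normalization. Without a known strand setting, reads of overlapping and antisense genes cannot be told apart, and reads that align to several places are left out of gene counts, which lowers the counts of near-identical gene copies.

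Genotype came from the labels, and replicates were numbered in accession order within a group, so the numbers only name samples. Counter totals in the table that name no gene were left out of library sizes and tests. Reads in no annotated gene made up 8.81% to 12.8% of a library's table total, ambiguous reads 2.02% to 2.2% and reads aligned to more than 1 place 23.4% to 28.6%. Reads assigned to genes numbered 29435651, 35332008 and 37722325 in Stag2KO replicates 1, 2 and 3 and 36976756, 36031809 and 33800670 in Stag2WT replicates 1, 2 and 3. At 5 CPM (gene reads scaled to a common library size) the shallowest library holds about 147 reads, which gives a counting error of 8.24%. That error covers counting only, since amplified reads are not independent molecules. All 6 libraries were kept because the labels list them as separate samples. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 22.6 to 47.1, which separately prepared libraries of 1 sample could also show.

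Counts were tested in R 4.3.3 with edgeR 4.0.16, using TMM normalization, the filterByExpr function with default settings, a robust quasi-likelihood fit with genotype as the only term, and Benjamini-Hochberg adjustment over 15708 genes. Genes with an adjusted p under 0.05 were called. Standard errors come from the same fit, and CPM values of single genes use TMM-scaled library sizes. Summed olfactory and vomeronasal receptor reads and the counting error at 5 CPM use unscaled gene reads. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, two-sided, with an inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 27 lists with at least 5 tested members. These lists cover B, T, natural killer, plasma, dendritic, monocyte and macrophage, neutrophil, eosinophil, erythroid, megakaryocyte, stem, endothelial and stromal cells. They also cover cohesin, PU.1 targets, cell cycle, histones, p53, MYC, interferon, immediate early, heat shock and mitochondrial genes. A list of Xist and Y-linked genes was only described. Single values were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 samples is 0.1.

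Groups, designs, lists and the naming rule were fixed before the data were examined. The rule named Stag2 and the cohesin genes, and 12 lineage transcription factor genes whatever their result. It named the 12 largest rises and 12 largest falls among called genes whose groups do not overlap and whose mean is at least 5 CPM, leaving out receptor gene segments, sex-linked genes and unnamed or numbered gene models. It also named up to 4 members with the smallest p of each list, of which some are not reported here. Other members and genes outside this rule were picked after their values were seen. Symbols missing from the table were dropped, and Spi1 was found as Sfpi1 through RefSeq synonyms. Neighbouring genes were taken from the gene order of the GRCm38 assembly, with 95.3% of tested genes placed; no coordinates are given because the table was made on another build.

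The fits were tested on simulated data drawn from these libraries' means and sizes, with 15481 genes run. For Stag2KO against Stag2WT, edgeR recovered 46.3% of genes changed 1.5-fold, 60.6% of those changed 2-fold and 95.5% of those changed 4-fold. False calls made up 11.8% of its calls, above the nominal 5%, against 8.82% for limma-voom and 22.9% for DESeq2. These shares come from a single draw with 67 genes changed 1.5-fold, 66 changed 2-fold and 66 changed 4-fold. The real comparison called 3333 genes, so neither the recovered nor the false shares carry over to it.

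Alternatives were median-ratio size factors, no filter beyond 1 read, a filter of 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit without robust dispersion and each library left out in turn. For lists they were an estimated correlation, the rotation test fry and the removal of genes in more than 1 list. The share of reads in no annotated gene as a covariate, the matching of older symbols and families grouped by symbol were added after the data were seen.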

Results

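RNA sequencing was carried out on mouse bone marrow from which cells carrying markers of mature blood lineages had been removed with magnetic beads. What remains after such a depletion is a mixture of stem cells, progenitors and some maturing cells, so each value is an average over mixed cells. Of the 6 libraries, 3 came from marrow labelled Stag2KO and 3 from marrow labelled Stag2WT. Stag2 encodes a subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops. The libraries held from 29435651 to 37722325 reads assigned to genes, and 15708 of 33924 listed genes were expressed highly enough to be tested. The labels do not say whether the samples of a group came from separate animals, so the p-values measure only the spread between these samples. On log2 CPM (gene reads scaled to a common library size), libraries of the same group correlated at 0.988 or more across genes and libraries of different groups at 0.976 or less. All 6 libraries carried transcripts of the Y chromosome, with 1216 to 1642 Uty reads, and at most 33 Xist reads. Reads in no annotated gene made up 11.7% ± 0.984 of the Stag2KO libraries and 9.24% ± 0.725 of the Stag2WT libraries (SD, n = 3 each). The nuclear RNAs Neat1 (log2 fold change 0.83, adjusted p = 0.00637) and Malat1 (0.81, adjusted p = 0.0421), both looked up after other values had been seen, were also higher in Stag2KO. The Malat1 call was lost without Stag2KO replicate 3 (adjusted p = 0.0639) and without Stag2WT replicate 1 (0.0501), 2 (0.121) or 3 (0.101).

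The first question was how far the targeted gene itself had fallen. Stag2 stood at 179.6 ± 9.25 CPM in the Stag2KO libraries and 330.2 ± 7.18 CPM in the Stag2WT libraries (SD, n = 3 each), so 54.4% of the Stag2WT level remained. The 3 Stag2KO libraries held 169, 187 and 183 CPM, each below the 338, 329 and 324 CPM of the Stag2WT libraries. The fitted log2 fold change was -0.88 (SE 0.06, adjusted p = 0.000278 by edgeR's quasi-likelihood test), and the two-sided exact permutation p of 0.1 was the smallest that 3 against 3 samples allow. Reads were counted over whole genes, so a transcript that lacks part of its exons is still counted. Stag1, which encodes the alternative subunit, was at 143 ± 6.82 CPM in Stag2KO and 129.8 ± 4.23 CPM in Stag2WT (log2 fold change 0.14, adjusted p = 0.14) and did not pass the test.

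Among the other cohesin genes, Esco2, an acetyltransferase acting on cohesin in S phase, fell (log2 fold change -0.48, adjusted p = 0.00745). Wapal, the cohesin release factor, fell by 0.31 on the log2 scale (adjusted p = 0.0206), and Rec8, a meiotic subunit, fell by 1.21 (adjusted p = 0.0466). The core genes Smc1a (-0.06, adjusted p = 0.447), Smc3 (-0.09, adjusted p = 0.282) and Rad21 (-0.09, adjusted p = 0.274) did not pass the test. Neither did the loader genes Nipbl (0.17) and Mau2 (0.14), the regulators Pds5a (0.00), Pds5b (0.13), Esco1 (0.03), Cdca5 (-0.22), Sgol1 (-0.25) and Hdac8 (-0.01), the meiotic Stag3 (-0.22), or Ctcf (-0.05). Of 18 tested members of this list, 4 were lower, Stag2 itself among them, 0 higher and 14 not called, and 4 were lower when adjusted over the list alone. The list as a whole was not called (camera adjusted p = 0.0705, and adjusted p = 0.589 with an estimated correlation). It was called lower without Stag2KO replicate 2 (0.0446) and by the rotation test fry (0.0255). The targeted Stag2 is itself a member and the list was not tested without it, so these calls do not show a fall of the other members. The Rec8 call held only without Stag2KO replicate 1; leaving out any other library gave adjusted p from 0.0779 to 0.14. The Wapal call was lost without Stag2KO replicate 1 (adjusted p = 0.0661) or replicate 3 (0.0803).

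**Figure D1:**
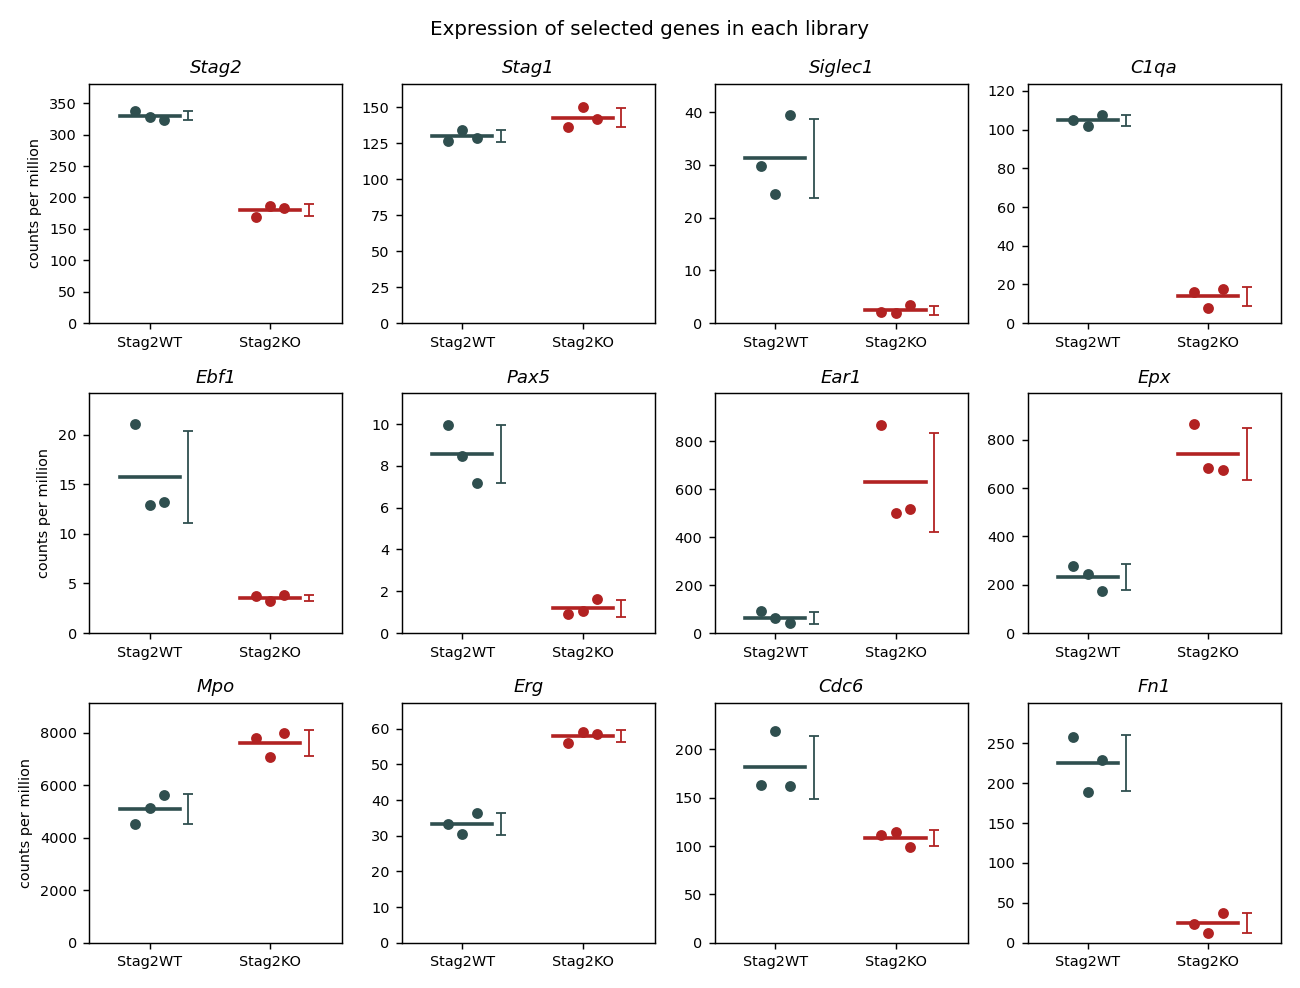
CPM (vertical axes, linear and starting at 0) of 12 genes in each library. Points are the 3 Stag2WT (dark) and 3 Stag2KO (red) libraries, horizontal lines are means and the bars beside them span 1 SD above and below the mean. Stag2 stays above 160 CPM in every Stag2KO library, while Siglec1, C1qa, Ebf1, Pax5 and Fn1 fall to a small part of the Stag2WT level and Ear1, Epx, Mpo and Erg rise.

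The next question was which genes differ between Stag2KO and Stag2WT marrow, in a series about cohesin in the self-renewal and differentiation of blood stem cells. Among called genes with a mean of at least 5 CPM, Siglec1 and Mrc1 were 2 of the 12 largest falls. Siglec1, a macrophage sialic acid receptor, dropped from 31.2 ± 7.55 to 2.48 ± 0.859 CPM (log2 fold change -3.65, SE 0.29), and the mannose receptor gene Mrc1 from 117 ± 12.97 to 11.3 ± 3.5 CPM (-3.38, SE 0.25). The 12 largest rises included 3 eosinophil-associated ribonuclease genes, led by Ear1, which went from 63.9 ± 24.7 to 628 ± 206 CPM (3.30, SE 0.41). In all, 3333 of 15708 genes were called at an adjusted p under 0.05, 1686 higher and 1647 lower in Stag2KO. More than 2-fold changes numbered 392 upward and 585 downward. The 3 values of one group lay wholly outside those of the other for 43.5% of tested genes, where chance gives 10% for a single gene. Genes are not independent replicates, so this share cannot serve as a test.

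Under the naming rule, the 12 largest rises were Fam71b (4.25), Eif5al3-ps (3.96), Nlrp1b (3.31), Ear1 (3.30), Ear2 (2.85), Serpinb2 (2.72), Ear6 (2.68), Chit1 (2.56), Alox12e (2.50), Fah (1.91), Olfm4 (1.82) and Esr1 (1.81), as log2 fold changes. Nlrp1b encodes an inflammasome sensor and Esr1 the estrogen receptor alpha, which rose from 19.6 ± 2.64 to 69.0 ± 2.44 CPM. Serpinb2 encodes a plasminogen activator inhibitor, Chit1 a chitinase and Olfm4 a secreted granulocyte protein. The 12 largest falls were Col14a1 (-6.62), Aldh1a7 (-3.98), Siglec1 (-3.65), Mrc1 (-3.38), Fcna (-3.36), Kcnj10 (-3.35), Fn1 (-3.21), Itgad (-3.18), Cnn3 (-3.07), Itga1 (-2.94), C1qa (-2.92) and Rag1 (-2.81). Col14a1 encodes a fibril-associated collagen and stood at 0.252 ± 0.02 CPM in Stag2KO against 25.04 ± 9.01 in Stag2WT. Fn1 encodes fibronectin, Fcna a macrophage lectin, Itgad and Itga1 integrin alpha subunits, and Rag1 the recombinase of lymphocyte receptor genes. Adjusted p-values of these 24 genes ran from 5.89e-05 to 0.0368. Ear1, Ear2 and Ear6 are near-identical copies, Eif5al3-ps is a pseudogene and Nlrp1b has close paralogs, so the split of reads among copies is uncertain. The numbered gene model Gm11942, left out by the rule and picked after its values were seen, rose more than any of these (6.67, from 0.989 to 101 CPM). Some gene models, receptor gene segments or sex-linked genes were left out by symbol although they met the rule's other conditions. Of these, 8 rose more than Esr1 and 1 fell more than Rag1. Genes with a mean under 5 CPM are not in these counts.

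Leaving out 1 library lowered the count of called genes to 2044 without Stag2KO replicate 1, 2016 without replicate 2 and 1967 without replicate 3, and to 1990 without Stag2WT replicate 2; it was 2484 without Stag2WT replicate 1 and 2548 without replicate 3. With the share of reads in no annotated gene as a covariate, chosen after the data were seen and correlated with genotype at 0.868 over the 6 libraries, 67 genes were called. Of the 24 genes above, Fah lost its call in 5 of the 6 fits that left out 1 library (adjusted p 0.081 to 0.121). Fah kept the call only without Stag2KO replicate 1. In that fit Fn1 lost its call (log2 fold change -3.20, adjusted p = 0.0565). Fits without 1 library have fewer samples and so less power. A call can be lost there with the fold change little moved, as for Fn1, at -3.21 in the full fit.

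**Figure D2:**
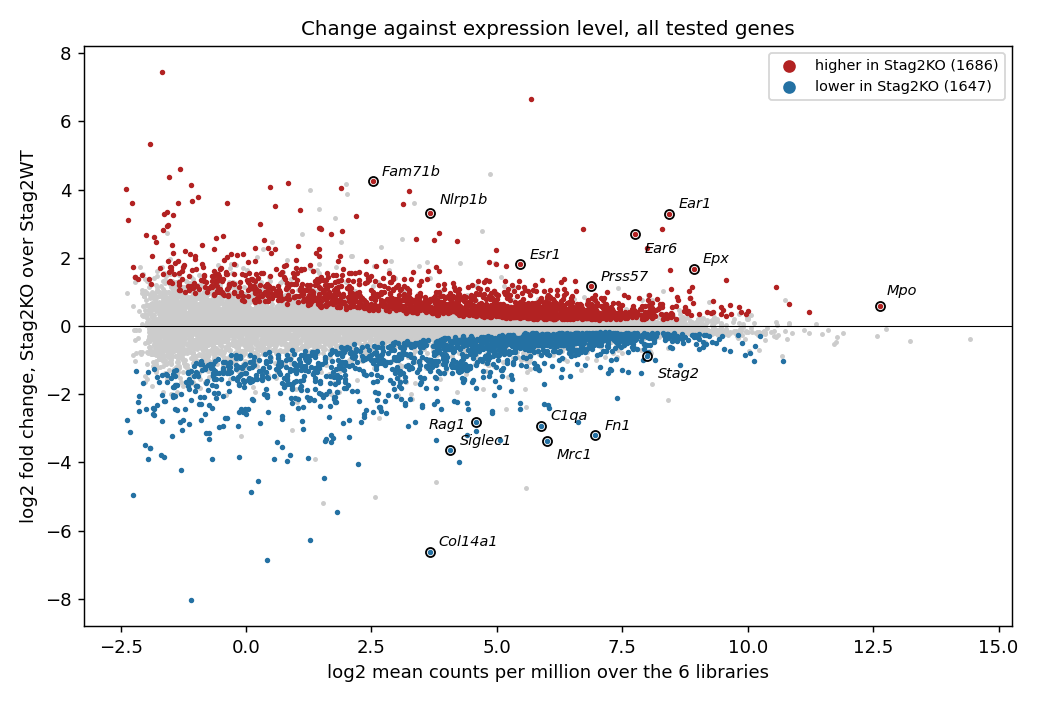
Log2 fold change of Stag2KO over Stag2WT (vertical axis) against the log2 of mean CPM over the 6 libraries (horizontal axis) for the 15708 tested genes. Red points are the 1686 genes called higher, blue points the 1647 called lower and grey points those not called; circles mark labelled genes.

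Genes of monocytes and macrophages fell broadly. Besides Siglec1, the scavenger receptor gene Cd163 dropped from 74.2 ± 11.2 to 13.7 ± 1.21 CPM (log2 fold change -2.44, adjusted p = 7.25e-05), the adhesion gene Vcam1 from 282 ± 20.5 to 109.9 ± 20.9 CPM (-1.36, adjusted p = 0.00154) and F13a1, a monocyte gene, from 323 ± 29.0 to 161 ± 10.9 CPM (-1.01, adjusted p = 0.00057). The complement gene C1qa fell as well, and so did C1qb (-2.27) and C1qc (-2.41), picked after their values were seen. Of 23 tested members 18 were lower, 0 higher and 5 not called, and 19 were lower when adjusted over the list alone. The list was called lower (camera adjusted p = 1.15e-10; adjusted p = 0.589 with an estimated correlation). Csf1r, the macrophage growth factor receptor gene, fell by 0.73, whereas the monocyte receptor gene Ccr2 had a log2 fold change of 0.77 and was not called. The share of reads in no annotated gene also differed between the groups, being 2.47 percentage points higher in Stag2KO. It therefore cannot be separated from genotype for these or the other genes.

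Genes of the bone marrow stroma and bone lineage fell alongside. Their levels were low, with a median of 6.17 CPM over the list's members in all libraries. Ibsp, encoding a bone matrix protein, fell by 2.02 on the log2 scale (adjusted p = 0.000372), the lipase gene Lpl by 1.78 (adjusted p = 0.00561) and the leptin receptor gene Lepr by 1.30 (adjusted p = 0.00192). Pdgfrb, a growth factor receptor gene of mural cells, rose (1.07, adjusted p = 0.00555). Of 22 members, 13 were lower, 1 higher and 8 not called; adjusted over the list alone the counts were 15 lower and 1 higher. The list was called lower (camera adjusted p = 3.37e-06; adjusted p = 0.589 with an estimated correlation). Endothelial genes went both ways, with 5 of 14 higher, 1 lower and 8 not called, the same counts when adjusted over the list alone. The sinusoidal scavenger receptor gene Stab2 fell by 1.39 (adjusted p = 0.00111). The vessel genes Emcn (0.70, adjusted p = 0.0203), Flt1 (0.74, adjusted p = 0.0238) and Tie1 (0.43, adjusted p = 0.032) rose. These 3 calls were lost without Stag2KO replicate 3, Stag2WT replicate 1 or Stag2WT replicate 2 (0.0503 to 0.081), those of Emcn (0.0574) and Tie1 (0.0953) without Stag2KO replicate 2, and those of Flt1 (0.0669) and Tie1 (0.0584) without Stag2KO replicate 1. The endothelial list was not called (camera adjusted p = 0.916; adjusted p = 0.937 with an estimated correlation), and its direction was downward by camera and upward by the rotation test fry.

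B lymphocyte genes fell. The B cell transcription factor genes Ebf1 (log2 fold change -2.14, SE 0.21, adjusted p = 0.000875) and Pax5 (-2.83, SE 0.25, adjusted p = 0.000645) were lower, Pax5 at 1.19 ± 0.403 against 8.55 ± 1.38 CPM. Vpreb3, a gene of early B cells, fell by 2.27 (adjusted p = 0.000635). Of 26 tested members 19 were lower, 0 higher and 7 not called, and 22 were lower when adjusted over the list alone (camera adjusted p = 1.49e-12; adjusted p = 0.589 with an estimated correlation). The immunoglobulin genes Ighm (-0.70, adjusted p = 0.284) and Igkc (-0.54) and the recombinase gene Rag2 (-0.51) were among those not called.

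Genes of lymphoid priming were mostly not called. The shared recombinase gene Rag1 fell, as did the E protein gene Tcf3 (log2 fold change -0.40, adjusted p = 0.00365) and the chemokine receptor gene Ccr7 (-1.68, adjusted p = 0.00459), while the chromatin organiser gene Satb1 rose (0.53, adjusted p = 0.0162). Of 20 members 5 were lower, 1 higher and 14 not called; adjusted over the list alone 7 were lower and 1 higher. The list was called lower (camera adjusted p = 0.00961; adjusted p = 0.633 with an estimated correlation), and 8 of its members belong to other lists as well. Without the shared members the list was not called (adjusted p = 0.165), nor with a CPM of at least 5 in at least 3 libraries (0.0851) or without Stag2WT replicate 1 (0.0513). The Satb1 call was lost without Stag2KO replicate 2 (adjusted p = 0.0535).

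T lymphocyte genes were at low levels and in part lower. Cd3g (log2 fold change -2.09, adjusted p = 0.00429), Cd3e (-1.61, adjusted p = 0.00744), Cd8a (-2.19, adjusted p = 0.0125) and Thy1 (-0.96, adjusted p = 0.00667) fell, the first 2 from under 5 CPM. Of 21 members 7 were lower, 0 higher and 14 not called, and 7 were lower when adjusted over the list alone (camera adjusted p = 0.000734; adjusted p = 0.633 with an estimated correlation). With a CPM of at least 5 in at least 3 libraries the list was not called (adjusted p = 0.17), and the Cd8a call was lost without Stag2KO replicate 2 (0.0536). Natural killer and innate lymphoid genes showed no such change, with 1 of 17 higher, 1 lower and 15 not called, the same counts when adjusted over the list alone (camera adjusted p = 0.546; adjusted p = 0.894 with an estimated correlation). Nkg7, a granule membrane gene also active in myeloid progenitors, rose by 0.58 on the log2 scale (adjusted p = 0.0065), and the chemokine gene Ccl5 fell by 1.35 (adjusted p = 0.00793), while the receptor gene Ncr1 (0.75, adjusted p = 0.0634) and the chemokine gene Xcl1 (0.73, adjusted p = 0.115) were not called. Without Stag2KO replicate 1 this list was called higher (adjusted p = 0.0379).

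Plasma cell genes were lower by list, with few members called. Irf4, a transcription factor gene of plasma cells, fell by 1.34 on the log2 scale (adjusted p = 0.00429), and the immunoglobulin gene Ighg2c fell by 2.11 (adjusted p = 0.0368). The syndecan gene Sdc1 fell by 0.60 (adjusted p = 0.0464), and Xbp1 (-0.20, adjusted p = 0.0893) was not called. Of 11 plasma cell genes 3 were lower, 0 higher and 8 not called, and 3 were lower when adjusted over the list alone (camera adjusted p = 0.0238; adjusted p = 0.633 with an estimated correlation). That list call was lost without Stag2WT replicate 1 (adjusted p = 0.0557) or replicate 2 (0.065). The Ighg2c call was lost without Stag2KO replicate 1 (0.109), 2 (0.107) or 3 (0.116) and without Stag2WT replicate 2 (0.0709). The Sdc1 call was lost without Stag2KO replicate 1 (0.121) or 3 (0.124) and without Stag2WT replicate 1 (0.118) or 2 (0.135).

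Among dendritic cell genes, Zbtb46, a transcription factor gene of classical dendritic cells, fell by 1.23 (adjusted p = 0.00114) and Cox6a2, a gene of plasmacytoid dendritic cells, by 1.31 (adjusted p = 0.00621). Batf3, a further factor gene of classical dendritic cells, fell by 1.18 (adjusted p = 0.0257), and the receptor gene Xcr1 (1.06, adjusted p = 0.126) was not called. Of 23 members 3 were lower, 0 higher and 20 not called, with 3 lower when adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.715 with an estimated correlation). Without Stag2KO replicate 1 (adjusted p = 0.167) or Stag2WT replicate 1 (0.066) the dendritic list was not called. The Batf3 call was lost without Stag2KO replicate 1 (0.0714) or 3 (0.0719) and without Stag2WT replicate 1 (0.0742) or 3 (0.0534).

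**Figure D3:**
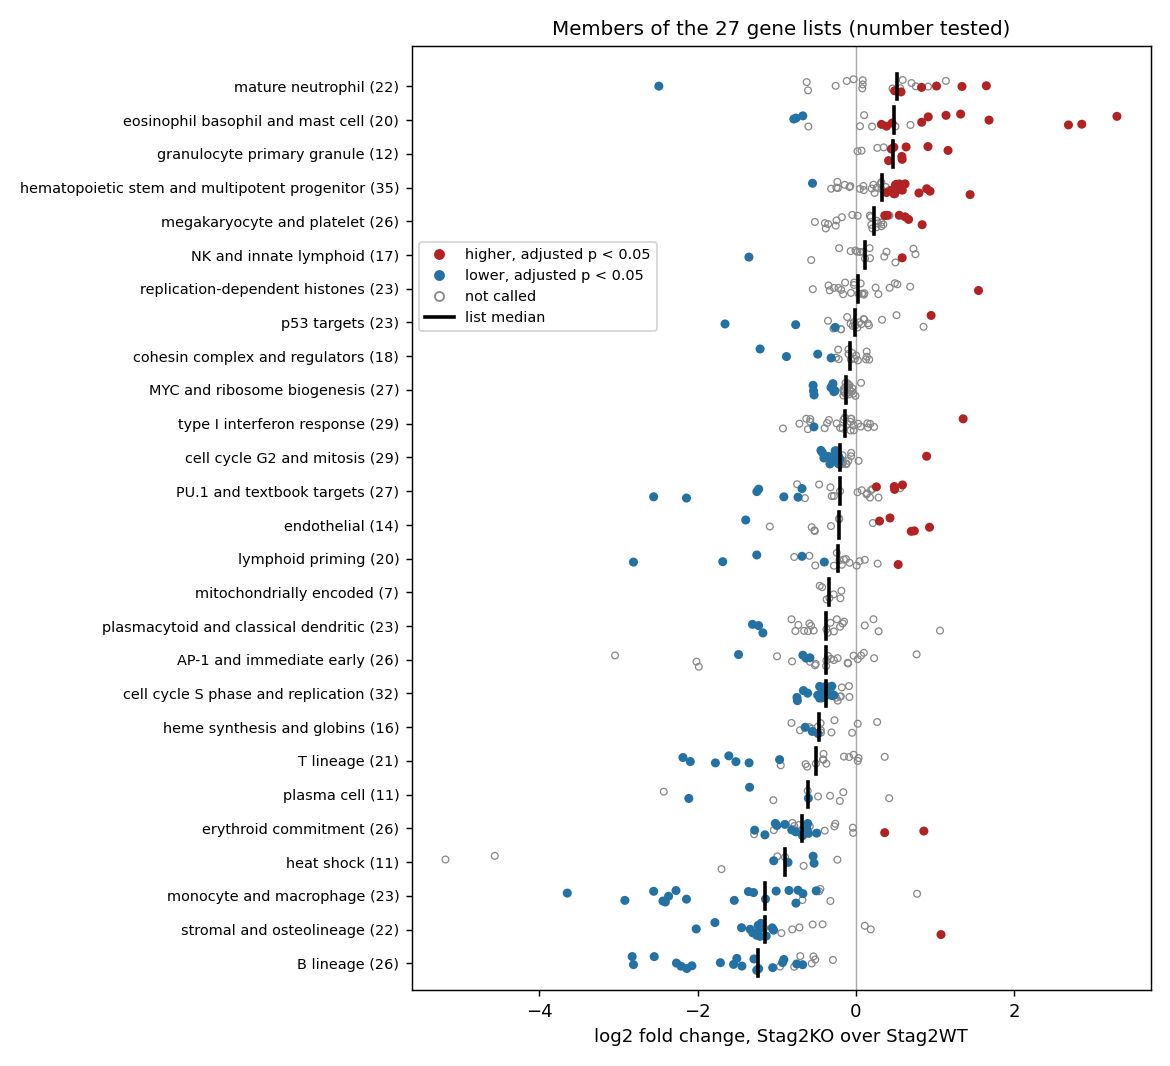
Log2 fold change of Stag2KO over Stag2WT (horizontal axis) for each tested member of 27 gene lists (vertical axis, number tested in parentheses, ordered by median). Red points were called higher, blue points lower, open points were not called and black bars are list medians; B lineage, stromal and macrophage genes lie lowest, with medians of -1.24, -1.15 and -1.14.

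Granule genes of eosinophils and of granulocyte precursors rose. The eosinophil peroxidase gene Epx went from 231 ± 53.3 to 741 ± 109 CPM (log2 fold change 1.68, SE 0.19, adjusted p = 0.00268), and Hdc, the histamine-synthesising enzyme gene, rose by 0.91 (adjusted p = 0.00057). The basophil protease genes moved the opposite way, Prss34 with a log2 fold change of -0.79 (adjusted p = 0.000833) and Mcpt8 with -0.67 (adjusted p = 0.00105). In the list of eosinophils, basophils and mast cells, 11 of 20 members were higher, 3 lower and 6 not called; adjusted over the list alone 14 were higher and 3 lower. That list was called higher (camera adjusted p = 0.00189; adjusted p = 0.589 with an estimated correlation). The primary granule genes Mpo (0.58, adjusted p = 0.0126) and Prss57 (1.16, adjusted p = 0.000835) rose, Mpo from 5093 ± 559 to 7611 ± 495 CPM. Of 12 primary granule genes 8 were higher, 0 lower and 4 not called, and 10 were higher when adjusted over the list alone (camera adjusted p = 0.000337; adjusted p = 0.589 with an estimated correlation). The Mpo call was lost without Stag2KO replicate 3 (adjusted p = 0.0506).

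Neutrophil genes of later stages gave a mixed picture. Fcnb, a ficolin gene of granulocyte precursors, rose by 1.65 on the log2 scale (adjusted p = 0.00432), the leukotriene receptor gene Ltb4r1 by 1.02 (adjusted p = 0.00336) and Anxa1 by 0.57 (adjusted p = 0.00134). The cytokine gene Il1b fell by 2.49 (adjusted p = 0.000853), while S100a8 (-0.26), S100a9 (-0.12), Ltf (0.09) and Mmp9 (0.09) were not called. Of 22 members 6 were higher, 1 lower and 15 not called; adjusted over the list alone 8 were higher and 1 lower. The list was called higher (camera adjusted p = 0.0198; adjusted p = 0.715 with an estimated correlation). That call was lost without Stag2KO replicate 1 (0.0956) or 3 (0.0625), without Stag2WT replicate 2 (0.0613) or 3 (0.0989), and without members of other lists (0.0571).

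Erythroid genes were lower in part. Aquaporin gene Aqp1 (log2 fold change -1.15, adjusted p = 0.0237), the carbonic anhydrase gene Car2 (-1.02, adjusted p = 0.0184) and the survival gene Bcl2l1 (-0.90, adjusted p = 0.00192) fell, while Nfe2 rose by 0.36 (adjusted p = 0.00563). The erythroid transcription factor gene Klf1 fell (-0.81, adjusted p = 0.044), and Gata1 was not called (-0.39, adjusted p = 0.121). Car2 stood at 1465, 1926 and 1101 CPM in Stag2WT replicates 1, 2 and 3. Replicate 2 was also highest for the replication gene Cdc6 (163, 219 and 162 CPM) and the chaperonin gene Hspd1 (510, 702 and 578 CPM). Bcl2l1 and Ftl1 were highest in replicate 1 instead. The erythroid, heme, replication, MYC and heat shock lists kept their calls without replicate 2, but may not be separate results. Of 26 members 12 were lower, 2 higher and 12 not called; adjusted over the list alone 22 were lower and 2 higher (camera adjusted p = 1.83e-05; adjusted p = 0.633 with an estimated correlation). Among heme and iron genes, Ftl1 (-0.48, adjusted p = 0.0235), Tmem14c (-0.64, adjusted p = 0.0335) and Cpox (-0.55, adjusted p = 0.0379) fell, and Fech (-0.44, adjusted p = 0.0539) was not called. Of 16 genes of heme synthesis and globins 3 were lower, 0 higher and 13 not called, with 5 lower when adjusted over the list alone (camera adjusted p = 0.00296; adjusted p = 0.633 with an estimated correlation). Without Stag2KO replicate 2 the calls of Aqp1 (adjusted p = 0.0723) and Car2 (0.0503) were lost. Klf1 kept its call only without Stag2WT replicate 2 or replicate 3, with adjusted p from 0.0837 to 0.124 in the other smaller fits. The Ftl1 call was lost without Stag2KO replicate 2 (0.0763) or 3 (0.0537) and without Stag2WT replicate 1 (0.0611) or 2 (0.0771). The Tmem14c call was lost without Stag2KO replicate 1 (0.0692), 2 (0.09) or 3 (0.0968). Its log2 fold changes in those fits were -0.68, -0.66 and -0.58, near that of the full fit. Cpox kept its call only without Stag2WT replicate 3 (0.0527 to 0.0933 otherwise). Without Stag2WT replicate 2 the log2 fold change of Cpox was -0.38.

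Genes of stem and multipotent cells rose in part. Erg, a transcription factor gene of stem cells, rose from 33.4 ± 3.04 to 57.9 ± 1.63 CPM (log2 fold change 0.80, SE 0.08, adjusted p = 0.00105). Runx1 (0.50, adjusted p = 0.00249) and Gata2 (0.39, adjusted p = 0.00588), further transcription factor genes of these cells, rose, as did Meis1 (0.55, adjusted p = 0.0206) and the repressor gene Gfi1 (0.48, adjusted p = 0.0136). The endoglin gene Eng fell by 0.55 (adjusted p = 0.00197). Hoxa9 (0.26, adjusted p = 0.332), Kit (0.05) and Ly6a (-0.14) were not called. Of 35 members 15 were higher, 1 lower and 19 not called; adjusted over the list alone 16 were higher and 1 lower. The list was called higher (camera adjusted p = 0.000433; adjusted p = 0.589 with an estimated correlation). The Meis1 call was lost without Stag2WT replicate 1 (adjusted p = 0.052) or replicate 2 (0.0676). Megakaryocyte genes included 6 of 26 higher, 0 lower and 20 not called, and 6 higher when adjusted over the list alone, among them the platelet receptor genes Gp5 (0.84, adjusted p = 0.00473) and Itgb3 (0.66, adjusted p = 0.007) and the factor gene Fli1 (0.36, adjusted p = 0.00769). The megakaryocyte list just missed the threshold (camera adjusted p = 0.0525; adjusted p = 0.715 with an estimated correlation), and it was called with no filter on low counts (0.0362), with the stricter filter (0.0176), without Stag2KO replicate 3 (0.0114) and without Stag2WT replicate 3 (0.00485).

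The gene of the myeloid and lymphoid factor PU.1, present under its older symbol Sfpi1, was at 145 ± 19.8 CPM in Stag2KO and 136 ± 9.16 in Stag2WT (log2 fold change 0.09, adjusted p = 0.558). Cebpa (0.02, adjusted p = 0.867) and Irf8 (-0.32, adjusted p = 0.343), which encode other myeloid transcription factors, were not called either. Among textbook targets of PU.1, Fcgr1, an antibody receptor gene of macrophages, fell by 2.56 on the log2 scale (adjusted p = 0.00276), Cebpb fell by 1.25 (adjusted p = 0.00954) and the B cell adaptor gene Blnk by 0.91 (adjusted p = 0.00316). Of 27 members 7 were lower, 4 higher and 16 not called; adjusted over the list alone 8 were lower and 5 higher. The list was not called (camera adjusted p = 0.304; adjusted p = 0.866 with an estimated correlation), and 12 of its members also stand in other lists. Without Stag2KO replicate 3 it was called lower (adjusted p = 0.0338).

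Genes of DNA replication fell by small amounts. Cdc6, which loads the replicative helicase, went from 181 ± 32.6 to 108.3 ± 7.9 CPM (log2 fold change -0.74, adjusted p = 0.00709). Uhrf1 (-0.46, adjusted p = 0.00502) and Pola1 (-0.38, adjusted p = 0.00613) fell less. Of 32 members 23 were lower, 0 higher and 9 not called, and 27 were lower when adjusted over the list alone (camera adjusted p = 2.72e-09; adjusted p = 0.589 with an estimated correlation). In the mitotic list 13 of 29 were lower, 1 higher and 15 not called, and adjusted over the list alone 16 were lower and 1 higher (camera adjusted p = 1.83e-05; adjusted p = 0.589 with an estimated correlation). The survivin gene Birc5 fell by 0.44 (adjusted p = 0.00635), the cyclin gene Ccna2 by 0.43 (adjusted p = 0.0122) and the centromere gene Cenpa by 0.40 (adjusted p = 0.00947), while the securin gene Pttg1 rose by 0.89 (adjusted p = 0.00501). Mki67 (-0.18) was not called. Replication-dependent histone genes had 1 of 23 members higher, 0 lower and 22 not called, with 1 higher when adjusted over the list alone (camera adjusted p = 0.645; adjusted p = 0.894 with an estimated correlation). Hist1h2ac rose by 1.54 (adjusted p = 0.00423), and Hist1h4i (-0.55), Hist2h4 (0.52) and Hist2h2ac (0.69) were not called. The histone list had a median level of 0.73 CPM over its members, against 128 CPM for the replication list. At such low levels a small shared fall would be hard to see.

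In the list of MYC targets and ribosome biogenesis, 8 of 27 members were lower, 0 higher and 19 not called, with 8 lower when adjusted over the list alone (camera adjusted p = 0.00107; adjusted p = 0.633 with an estimated correlation). The mitochondrial chaperonin genes Hspd1 (-0.54, adjusted p = 0.0165) and Hspe1 (-0.53, adjusted p = 0.0286) fell, as did the nucleolar genes Fbl (-0.29, adjusted p = 0.0245) and Nolc1 (-0.32, adjusted p = 0.0281). Without Stag2KO replicate 1 the calls of these 4 genes were lost (0.0531 to 0.0889), as they were without Stag2KO replicate 3 (0.0521 to 0.0921). Fbl (0.0656) and Hspe1 (0.0821) lost theirs also without Stag2KO replicate 2, Fbl (0.0597) and Nolc1 (0.0681) without Stag2WT replicate 2, and Fbl (0.0562), Nolc1 (0.0608) and Hspe1 (0.0545) without Stag2WT replicate 3.

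Among p53 targets, genes of cell cycle arrest and cell death, 3 of 23 were lower, 1 higher and 19 not called, the same counts when adjusted over the list alone (camera adjusted p = 0.526; adjusted p = 0.817 with an estimated correlation). The pro-apoptotic gene Pmaip1 fell by 1.65 (adjusted p = 0.00114) and the death receptor gene Fas rose by 0.95 (adjusted p = 0.0126), while the stress gene Sesn2 fell by 0.76 (adjusted p = 0.00509) and Gtse1 by 0.26 (adjusted p = 0.0431), a call kept only without Stag2KO replicate 1 (0.0766 to 0.161 otherwise). Type I interferon response genes had 1 of 29 members higher, 1 lower and 27 not called, and 0 in either direction when adjusted over the list alone (camera adjusted p = 0.201; adjusted p = 0.866 with an estimated correlation). The nucleotide kinase gene Cmpk2 fell by 0.53 (adjusted p = 0.0208) and Xaf1 rose by 1.35 (adjusted p = 0.0274), while Irf9 (-0.34, adjusted p = 0.0778) and Oasl1 (-0.61, adjusted p = 0.125) were not called. The Cmpk2 call was lost without Stag2KO replicate 2 (0.0682) or 3 (0.054) and without Stag2WT replicate 1 (0.0514) or 2 (0.0702). The Xaf1 call was lost without Stag2KO replicate 2 (0.0775) and without Stag2WT replicate 2 (0.0993) or 3 (0.08). The interferon list was called lower without Stag2KO replicate 3 (0.00227) or Stag2WT replicate 2 (0.0302).

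Heat shock and immediate early genes, which can respond to handling, were called in part, and some were uneven among the Stag2WT libraries. The chaperone gene Hsp90aa1 fell by 0.86 on the log2 scale (adjusted p = 0.00624), and Hspa8 by 1.04 (adjusted p = 0.0387), next to Hspd1 and Hspe1 of the same list. The Hspa8 call was lost without Stag2KO replicate 1 (0.0931), 2 (0.111) or 3 (0.0576) and without Stag2WT replicate 3 (0.0623). Hspa1b, an inducible chaperone gene, stood at 1.72, 49.3 and 28.2 CPM in Stag2WT replicates 1, 2 and 3 and at 1.88, 0.3 and 1.23 CPM in the Stag2KO libraries, and was not called. Of 11 heat shock genes 4 were lower, 0 higher and 7 not called, and 9 were lower when adjusted over the list alone (camera adjusted p = 0.000236; adjusted p = 0.589 with an estimated correlation).

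The immediate early gene Nr4a1 fell by 1.48 (adjusted p = 0.0017) and Jund by 0.63 (adjusted p = 0.0109), Klf4 by 0.67 (adjusted p = 0.0165) and Ppp1r15a by 0.58 (adjusted p = 0.0209). The Klf4 call was lost without Stag2KO replicate 2 (0.059), and that of Ppp1r15a without Stag2KO replicate 3 (0.0551) or Stag2WT replicate 2 (0.0629). Fos stood at 7.87, 28.2 and 11.1 CPM in the Stag2WT replicates and at 2.88, 3.19 and 5.79 CPM in the Stag2KO replicates, without passing the test. Of 26 immediate early genes 4 were lower, 0 higher and 22 not called, with 4 lower when adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.589 with an estimated correlation). Of 7 mitochondrially encoded genes none was called, also when adjusted over the list alone (0 higher, 0 lower; camera adjusted p = 0.133; adjusted p = 0.715 with an estimated correlation), and their reads made up 4.59% ± 0.951 of gene reads in Stag2KO and 5.81% ± 1.47 in Stag2WT. Among them mt-Cytb (-0.43), mt-Nd2 (-0.46), mt-Co1 (-0.37) and mt-Nd4 (-0.34) had the smallest p-values, and the list was called lower without Stag2KO replicate 1 (0.0327).

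Over the lists together, 18 of 27 were called, 4 higher and 14 lower, with the correlation among members preset at 0.01. With the correlation estimated from the 6 libraries 0 were called, the smallest adjusted p being 0.589. Many lists share that value through the adjustment. Unadjusted camera p-values were 0.0583 for monocytes and macrophages and 0.0714 for B cells. In simulated data a list of raised, independent genes had camera adjusted p = 0.0177 with an estimated correlation and 6.14e-43 with the preset one. The estimated version thus has less power, and a list it leaves uncalled is not shown to be unchanged. The rotation test fry, which asks whether the genes of a list move one way on balance, called 7 lists, 6 of the 18 and the cohesin list. The cohesin list includes the targeted Stag2. The version of fry for changes in either direction called 22.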

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

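The test of removal of mature cells, the covariate and the comparison with random subsets of smaller changes were chosen after the results they bear on, or other results of these data, had been seen. Malat1 and Neat1 were likewise looked up after other values had been seen. The remaining tests were fixed before their values were computed.

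Among counter totals, which the comparisons of genes do not use, reads in no annotated gene took 11.7% ± 0.984 of the Stag2KO libraries and 9.24% ± 0.725 of the Stag2WT libraries (SD, n = 3 each), a difference of 2.47 percentage points with an exact permutation p of 0.1, the smallest possible. A larger share of nuclear RNA may account for it, since Malat1 and Neat1 had a median log2 fold change of 0.82 (Kcnq1ot1 was not tested). Genomic DNA cannot be told apart from other causes. Summed olfactory and vomeronasal receptor reads were 15.6 to 22.1 CPM in Stag2KO and 10.6 to 16.2 in Stag2WT, and the lowest Stag2KO value lay -0.59 from the highest Stag2WT value with a counting error of 1.004. A different mixture of cells with the genotype stays open as well and was not tested.

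Monocyte and macrophage genes were lower in Stag2KO. More complete removal of all mature cells alike from the Stag2KO samples would lower each list of mature cells. The mature neutrophil list instead had a median log2 fold change of 0.52 (SE 0.23 over members, which are not independent). This cannot decide, because the list holds Fcnb, a gene of granulocyte precursors, and lost its call in several smaller fits. In it Il1b (-2.49) fell, and Ly6g, Mmp8, S100a8 and S100a9 lay below 0. Medians were 0.48 for eosinophils, basophils and mast cells and 0.11 for natural killer cells. They were -0.37 for dendritic, -0.51 for T, -0.60 for plasma and -1.24 for B cells, -0.68 for erythroid commitment and -0.46 for heme and globins. More complete removal of mature cells, of all or of some types, stays open. With the share of reads in no annotated gene as a covariate, the 18 called members had a median of -1.04 in place of -1.45. This cannot decide whether that share is the whole cause, since the members were picked as called in the same data. The covariate is correlated with genotype at 0.868 and the members' median SE went from 0.222 to 0.303, so the loss of most single calls in that fit does not separate the share from the genotype. Fewer macrophages or macrophage fragments passing the bead depletion, which is meant to remove such cells, and a lower share or altered expression with the genotype all stay open. Of the 23 genes 6 belong to other lists too. Vcam1 and F13a1 were the most abundant of the called members named, at 282 and 323 CPM in Stag2WT.

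Among called genes that changed over 2-fold, 326 pairs not sharing a symbol stem lay within 5 tested genes of each other in the GRCm38 gene order. A permutation test with 10000 expression-matched draws gave 280.5 on average (95th percentile 307, permutation p = 0.0032). The ratio to the draws was 1.16, against 1.04 for smaller changes, but 7 of 100 random subsets of those smaller changes held as many pairs. These subsets were not matched for expression as the draws were, so they cannot decide whether large changes lie closer together. Outside the fixed lists 271 pairs stood against 235.8 (permutation p = 0.0116). Of 100 tested genes around Stag2, 21% were called, against 21.9% of all placed genes. In the Nlrp1 cluster, picked after its values were seen, Nlrp1b was higher (3.31) and its neighbours Nlrp1a (-2.36) and Nlrp1c-ps (-2.42) lower; the Clec4 and Cd209 clusters also went both ways (Clec4b2 1.19 beside Clec4b1 -2.25, Cd209c 1.25 beside Cd209d -1.47), while others moved one way, such as C1qa, C1qb and C1qc downward and Ear1 and Ear2 upward. Chromosome segments of another mouse strain carried by 1 group may account for part of this; clusters of genes active in the same cell type would give neighbours too, and reads would be needed to separate them.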

How the results depend on the processing

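The covariate, the matching of older symbols and the symbol families were chosen after the data were seen. The count of 3333 called genes (1686 higher, 1647 lower) was 3322 with median-ratio size factors, 3320 without a filter, 2552 with the stricter filter, 3887 with DESeq2 (617 adjusted p not given), 3211 with limma-voom and 3259 without robust dispersion. Leaving out each library gave 1967 to 2548 genes, 962 to 1256 higher and 902 to 1311 lower, from fewer samples. With the share of reads in no annotated gene as a covariate, 67 genes were called, 44 higher and 23 lower. Of the 3333 genes, 3323 had the same sign in that fit. The median absolute log2 fold change of the 3333 genes was 0.53 in place of 0.60 and their median SE 0.243 in place of 0.121. These genes, like the called list members that follow, were picked as called in the same libraries. Kept signs and sizes therefore cannot serve as a test. Medians of called list members shifted more in some lists, from -1.23 to -0.70 for stromal, 0.56 to 0.20 for endothelial and 0.83 to 1.43 for mature neutrophil genes. Others shifted less, such as erythroid commitment genes from -0.72 to -0.64. Of the 10 splits of the libraries into 3 and 3, 1, the real one, called as many as 3333 genes by edgeR and the highest of the others called 0; 10 splits cannot give a share under 0.05. Stag2 was called lower under each setting that keeps the genotype groups, with the covariate at an adjusted p of 0.0453. Of the 18 called lists 0 were called with an estimated correlation and 6 with fry, which asks another question and called 7 in all. The other was the cohesin list, which includes Stag2 itself. With a library left out 15 to 20 lists were called. Of the 18 lists, 14 were called in each fit that left out 1 library. Of 126 called genes among those named, 31 lost the call in at least 1 such fit, 104 with the covariate and 10 without a filter (Fah, Rec8, Aqp1, Tmem14c, Cpox, Xaf1, Hspa8, Ighg2c, Klf1 and Malat1); Sdc1 and Fah lost it with limma-voom, and Sdc1 also with the stricter filter and without robust dispersion. No paired analysis was possible because the labels pair no samples. Depth limits genes under 5 CPM most, where counting error exceeds 8.24% in the shallowest library.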

Other observations

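The gene families here were grouped by symbol after the data were seen, and the protocadherin genes were picked because single members had been seen to rise. Among cytosolic chaperonin genes 7 of 8 were lower, 0 higher and 1 not called, such as Cct8 (log2 fold change -0.40, adjusted p = 0.0169), with camera adjusted p = 0.00588. This family, like each of the next 4, had adjusted p = 0.666 with an estimated correlation. Proteasome subunit genes had 15 of 38 lower, 0 higher and 23 not called (camera adjusted p = 5.47e-06). Ribosomal protein genes had 10 of 78 lower, 1 higher and 67 not called (camera adjusted p = 1.1e-07), and genes of mitochondrial NADH dehydrogenase 10 of 36 lower, 0 higher and 26 not called (camera adjusted p = 5.36e-05). Zinc finger genes named Zfp went the other way, with 46 of 330 higher, 9 lower and 275 not called (camera adjusted p = 0.000741). Of 20 families computed 9 were called, and 0 with an estimated correlation; the 9 include the protocadherin genes, whose choice fixed that outcome. Most members of the proteasome, ribosomal protein, NADH dehydrogenase and Zfp families were not called. Single members of these families were not examined with a library left out.

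Clustered protocadherin beta genes, which encode neuronal adhesion proteins and whose promoters are known to depend on CTCF and cohesin, were expressed at low levels. Of 5 tested members 4 rose and 1 was not called, a count that cannot serve as a test because the genes were chosen for their rise; among them were Pcdhb16 from 0.435 to 1.61 CPM (log2 fold change 1.88, adjusted p = 0.0125) and Pcdhb5 (2.92, adjusted p = 0.0175), the latter with 12, 32 and 19 reads in the Stag2KO libraries and 4, 0 and 4 in the Stag2WT libraries. Of single genes picked after their values were seen, Stfa1, encoding a cysteine protease inhibitor of myeloid cells, had 256, 209 and 252 reads in the Stag2KO libraries and 6, 21 and 17 in the Stag2WT libraries. The lectin gene Cd209f, picked in the same way, had 4, 0 and 2 reads in Stag2KO and 64, 224 and 211 in Stag2WT. Collagen genes had 10 of 30 members lower, 2 higher and 18 not called (camera adjusted p = 0.000397; adjusted p = 0.666 with an estimated correlation).

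One hypothesis, fixed before its value was computed, was that long genes fall when cohesin is reduced. Across 14972 tested genes Spearman's rho between genomic span and log2 fold change was 0.0425, so the relation it needs, below -0.1, was not seen; genes are not independent replicates.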
